A study of Arabidopsis thaliana with 24 samples.

How the data were processed

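Messenger RNA of whole Arabidopsis thaliana seedlings was sequenced in 24 libraries, 3 for each combination of genotype (cpd or the bri1-701 brl1 brl3 triple mutant), age (7 or 24 days) and treatment (none or brassinolide, BL). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The values used are read counts per gene locus, which the authors deposited as whole numbers in 1 table with a column per library. Trimmomatic 0.36, HISAT2 2.1.0, HTSeq 0.9.1 and the TAIR10 build are named in the submitters' processing notes. The role and settings of each tool, the annotation release and the use of strand are not given in the sources used here. Counts of a gene that overlaps another gene on either strand can therefore hold reads of its partner. SAUR19 to SAUR24 and SAUR61 to SAUR68 are families of near-identical copies, and how reads shared between copies were counted is not given in the sources used here, so values of single members of those families are uncertain.

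The table holds 32678 loci and no total or unassigned line, and 0 of its library columns were left out. Of these loci 31912 were found in the reference annotation (TAIR10.1) and 10616 of them had a symbol. The reference is a later release of the build named by the submitters, so only chromosome numbers and symbols were taken from it. Total counts per library were 10180880 to 12531699 at 7 days and 17243503 to 20563151 at 24 days. A gene with 0 counts in a library is compatible with up to 3 counts, a floor of 0.239 to 0.295 CPM (counts scaled to the library total) per library at 7 days and 0.146 to 0.174 CPM at 24 days. For a fold against a group with 0 counts in all libraries, the floor of 3 counts was set over the group. Floors and intervals cover counting error only, since reads copied by PCR are not independent molecules.

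Groups were taken from the labels. The genotype label spells the first allele of the triple mutant brl1-701, whereas the design text spells it bri1-701, and the design text was followed. The dose of BL and the length of the treatment are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separately grown plants, so p-values measure the spread between these libraries, which may be technical. Counts were normalised with TMM factors and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10. Each age was fitted on its own with its 12 libraries in a cell-means model, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested gave the adjusted p-values, with a threshold of 0.05. The age interaction was tested in a fit of all 24 libraries. Directions are BL minus none, triple mutant minus cpd, BL effect in the triple mutant minus BL effect in cpd, and BL effect at 24 days minus BL effect at 7 days. Group levels are means of normalised CPM with the SD over 3 libraries. Log2 fold changes carry a standard error (SE) back-calculated from the test, as their absolute value over the square root of its F statistic. This SE can be too small for large changes to or from few counts. Examples are the changes of BR6OX2 and DWF4 with BL in cpd, and the interactions that include them.

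Before the data were examined, 21 gene lists with 295 members were fixed: BR biosynthesis, BR inactivation, BR signalling, growth bHLH factors, SAUR, expansins and xyloglucan enzymes, cellulose synthases, auxin response, ABA response and metabolism, gibberellin, photosynthesis, defence, jasmonate, glucosinolate biosynthesis, flavonoid and anthocyanin, cell cycle, circadian clock, floral transition and flower, root markers, senescence, and ethylene (BR, brassinosteroid; ABA, abscisic acid). Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. The fixed rule took members by symbol and locus. For 4 members (SAUR21, SAUR68, CHI and PAP2) the reference gives the symbol to another locus, and the locus written beforehand was kept, which departs from that rule. Named genes were chosen by a rule fixed beforehand. It takes CPD, BRI1, BRL1, BRL3 and ABI4 in every group, the 6 largest rises and 6 largest falls of each comparison among genes past the test with a mean of at least 5 CPM, a symbol and no overlap between groups, and up to 3 members per list with the smallest adjusted p.

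After the real fits, the tests were also run on simulated counts with 200 genes changed by known amounts. These counts used the library sizes, the fitted spread and 1 mean level per gene, pooled over all groups of the fit. A further gene list was changed for the list test. For the BL effect in cpd, 91% of simulated log2 changes of 1 were recovered at 7 days (18232 genes) and 77.6% at 24 days (19623 genes). For log2 changes of 0.5 the shares were 79.1% and 22.4%. Of the genes called in these simulations 3.96% and 6.76% had not been changed. For the genotype by BL interaction, 46.3% of simulated log2 changes of 1 were recovered at 24 days (19628 genes) and 76.1% at 7 days (18247 genes). For the age interaction 55.2% were recovered (19664 genes). For log2 changes of 0.5 these shares were 0%, 50.7% and 22.4%. Simulated libraries were drawn independently and few genes were changed. Genes that were low in only some real groups were simulated at their pooled level. The real 24-day libraries correlated by replicate number, and 10524 of 18378 genes were called for BL in 7-day cpd. The shares of these simulations therefore need not hold for the real tests.

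Whether replicate numbers pair the libraries was checked by correlating deviations from the group means across genes, for libraries with the same number in the groups compared. At 24 days these correlations lay between 0.13 and 0.616, all above the limit of 0.1, and at 7 days between -0.026 and 0.041. The 24-day numbers were therefore taken to pair the libraries, although the labels name no shared batch or day. Between groups that differ in both genotype and BL, replicate 1 correlated with replicate 1 at only 0.083 and 0.086. Differently numbered libraries reached 0.281, for replicate 2 of untreated cpd and replicate 1 of the untreated triple mutant. The main 24-day fits do not use the pairing, so their p-values and counts ignore it, and only the replicate block takes it in. Alternatives planned before the data were examined were RLE size factors, no filter on low counts, a replicate block, each library left out in turn, a fit of the compared groups alone, a fit of all 24 libraries, DESeq2 1.42.0, and for the overlap of calls a threshold of 0.01. Added after the data were seen were the 24-day spread applied to the 7-day counts, replicate 3 left out of every 24-day group, and list tests with the replicate block and without replicate 2 of the untreated triple mutant at 24 days. The 24-day spread was set as a fixed dispersion per gene in edgeR's likelihood ratio test, which replaced the quasi-likelihood test. Genes not tested at 24 days took the common 24-day dispersion.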

Results

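Seedlings of 2 Arabidopsis genotypes were compared with and without BL, the most active brassinosteroid. The cpd mutant carries a defect in CPD (CYP90A1), a cytochrome P450 of BR biosynthesis, and can still perceive the hormone. The triple mutant carries defects in BRI1, the main BR receptor, and in its homologues BRL1 and BRL3. The series title concerns the role of the transcription factor ABI4 in the BR response, and the design asks which transcripts respond to BL in a hormone-deficient and in a receptor mutant at 7 and at 24 days. The 8 groups held 3 libraries each, with 10180880 to 12531699 counts per library at 7 days and 17243503 to 20563151 at 24 days. The 10 most abundant genes took 3.31% to 4.2% of the counts of a library, and plastid and mitochondrial genes took at most 0.0623% and 0.0229%.

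Replicates at 7 days lay close together. Their counts differed by 1.13 to 1.51 times the variance that counting alone gives (chi-square per degree of freedom over 12 pairs of replicates), against 6.38 to 59.1 times at 24 days. The biological coefficient of variation was 2.01% at 7 days and 15% at 24 days, so the same fold change passed the test more readily at 7 days. The first principal component of the 7-day libraries (56.8% of the variance) set BL-treated cpd apart from the other groups. At 24 days the first component (40.7%) ran from the triple mutant to BL-treated cpd, and the second (22%) was highest in replicate 3 within each of the 4 groups. Root marker genes also had their highest median in replicate 3 of each 24-day group, 0.45, 0.28, 0.20 and 0.28 log2 units above the mean of untreated cpd, untreated triple mutant, BL-treated cpd and BL-treated triple mutant.

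**Figure D1:**
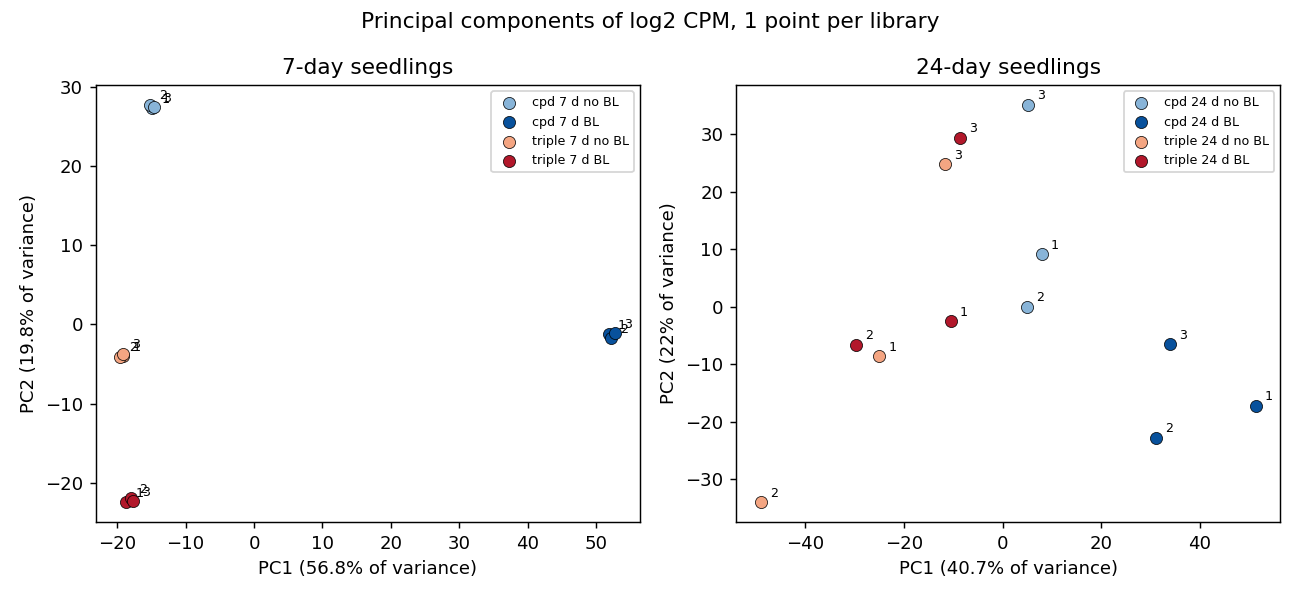
Principal components of log2 CPM for the 12 libraries of each age, with the share of variance on each axis. Points are libraries coloured by group and numbered by replicate, and BL-treated cpd lies at the high end of the first component at both ages (56.8% of the variance at 7 days, 40.7% at 24 days).

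The mutated genes were examined first. CPD (AT5G05690, chromosome 5) had 68.3 ± 3.5 CPM (SD, n = 3) in untreated 7-day cpd and 434 ± 4.5 CPM in the untreated triple mutant. At 24 days the levels were 113 ± 5.7 and 380 ± 44 CPM. BRI1 (AT4G39400, chromosome 4) had 169 ± 5.4 CPM in untreated 7-day cpd against 48.3 ± 1.7 CPM in the triple mutant, and 271 ± 12 against 65.3 ± 4.2 CPM at 24 days. BRL1 (AT1G55610, chromosome 1) fell in the triple mutant by 1.69 ± 0.16 (SE) on the log2 scale at 7 days and BRL3 (AT3G13380, chromosome 3) fell by 3.79 ± 0.12. At 24 days BRL1 fell by 1.21 ± 0.14 and BRL3 fell by 2.48 ± 0.20. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the largest adjusted p among the 4 genes was 3.44e-14 at 7 days and 0.00393 at 24 days. The positions of the mutations are not given in the sources used here, so reads from intact parts of a mutated gene are included. ABI4 (AT2G40220, chromosome 2) had 0 counts in all 24 libraries, which allows up to 0.295 CPM in a 7-day library and up to 0.174 CPM in a 24-day library. ABI4 was not detectable at this depth and was not tested.

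**Figure D2:**
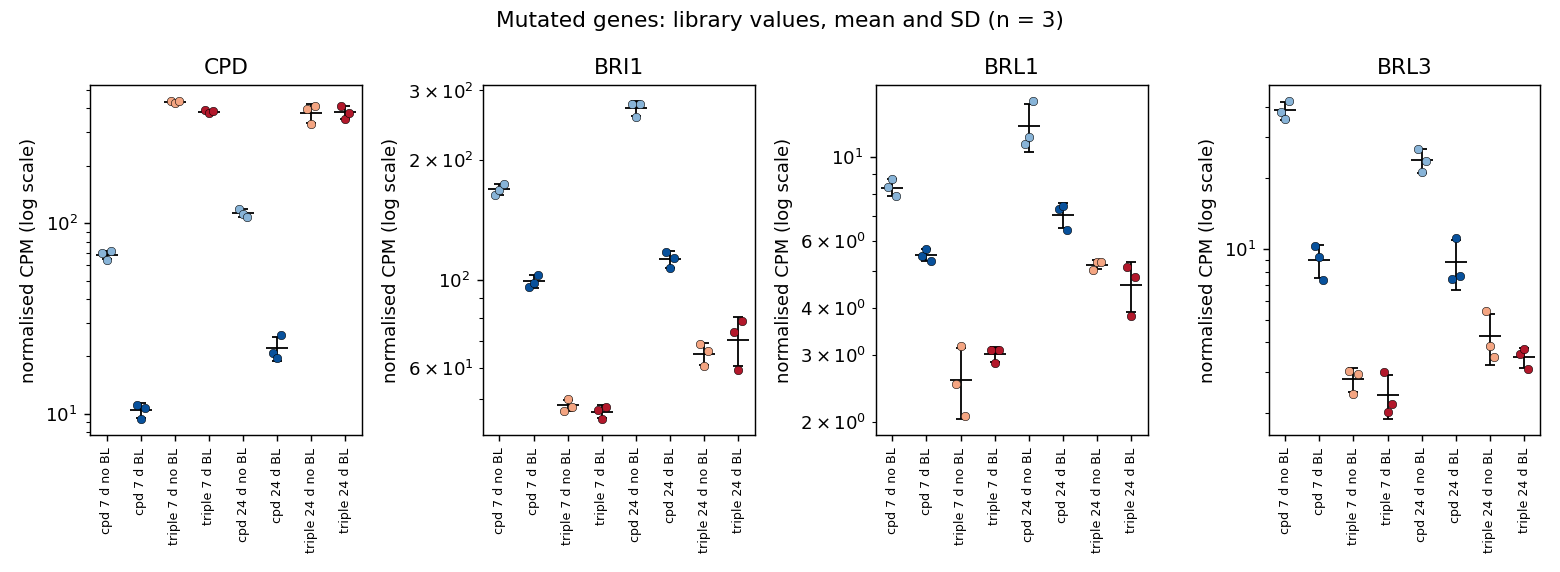
Normalised CPM (log scale) of CPD, BRI1, BRL1 and BRL3 in the 8 groups, with points for libraries, horizontal ticks for means and bars for SD (n = 3). CPD lies at 434 CPM in the untreated 7-day triple mutant and at 10.4 CPM in BL-treated 7-day cpd, and the mean of BRI1 is at most 70.7 CPM in the triple mutant groups.

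In 7-day cpd, BL lowered transcripts of BR biosynthesis and raised growth-related transcripts. BR6OX2, which makes BL itself, went from 134 ± 4.7 to 0.958 ± 0.49 CPM (SD, n = 3), a 137-fold fall (log2 -7.10 ± 0.10, SE). Its SE, back-calculated from the test, is likely too small, since few BR6OX2 counts remained with BL. DWF4 and ROT3, hydroxylases of the same pathway, fell 44.1-fold and 40.2-fold, and CPD fell 6.57-fold. PRE6, a growth-promoting bHLH factor, rose 22.8-fold from 3.5 ± 0.33 to 80.2 ± 3.8 CPM, the arabinogalactan protein gene AGP4 rose 21.8-fold and the xyloglucan enzyme gene XTH8 rose 18.3-fold. The peptide gene RGF6 rose 11-fold and the expansin gene EXPA11 rose 9.99-fold. MYB55, the amido synthetase gene GH3.17 and MYB122 fell 31.2-fold, 14.7-fold and 11.6-fold. The largest adjusted p among these genes was 9.72e-30.

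By list, 5 of 6 BR biosynthesis genes fell and all 16 SAUR genes, which promote cell expansion, rose. SAUR66, SAUR22 and SAUR16 rose 7.52-fold, 9.11-fold and 4.6-fold. SAUR10, SAUR15 and SAUR68 had 0 counts in untreated cpd and were at least 11-fold, 26.7-fold and 36-fold higher with BL. The SAUR median was log2 3.90 with these 3 genes at their bounds and 4.17 with fitted values. With SAUR21 and SAUR68 taken at the loci that carry those symbols in the reference, 14 of 15 SAUR genes rose and 1 fell. Among growth bHLH factors 6 of 8 rose and 1 fell, IBH1, an inhibitor of cell elongation (log2 -1.69 ± 0.07). HBI1 rose by log2 1.11 ± 0.05. Of the cellulose synthases 5 of 8 rose, with CESA3 at log2 0.71 ± 0.02 and CESA2 at 0.89 ± 0.03. Photosynthesis genes rose in 20 of 21 cases by a median of log2 0.43, among them RBCS2B (1.04 ± 0.03). Lower lists were jasmonate (12 of 14 fell, 1 rose; JAZ1 -1.12 ± 0.03, LOX2 -1.24 ± 0.03), glucosinolate biosynthesis (10 of 14 fell, 1 rose; MYB51 -1.13 ± 0.03) and ABA response and metabolism (13 of 18 fell, 2 rose; KIN1 -1.30 ± 0.06). Senescence (7 of 8 fell, 1 rose; the phosphatase gene SAG113 -2.36 ± 0.08), ethylene (7 of 9 fell, 1 rose; ACS8 -0.96 ± 0.04) and defence (8 of 13 fell, 4 rose; WRKY40 -2.52 ± 0.03) were also lower as lists. For these 11 lists camera gave adjusted p-values of at most 0.0017, and of at most 0.02 with an estimated correlation.

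Among expansins and xyloglucan enzymes in 7-day cpd, 9 of 14 rose and 4 fell, with XTH4 at log2 2.73 ± 0.03 and XTH24 at -1.46 ± 0.02 (camera adjusted p = 0.09). BR signalling had 7 of 19 higher and 8 lower, among them BEH2 (-3.20 ± 0.05) and BES1 (1.23 ± 0.06), which encode related transcription factors of the pathway. BR inactivation had 3 of 5 higher and 2 lower, with BAS1 at 1.26 ± 0.11 and UGT73C5 at -1.10 ± 0.06. The auxin response list had 6 of 15 higher and 6 lower. Its median (log2 0.07) and mean (0.35) were positive, while camera placed it lower than other genes (adjusted p = 0.02, and 0.048 with an estimated correlation), and GH3.5 and IAA2 fell by 2.07 ± 0.03 and 1.13 ± 0.03. In the cell cycle list 6 of 12 rose and 1 fell, including the replication genes MCM2 (1.76 ± 0.17), MCM5 (1.51 ± 0.13) and PCNA1 (2.00 ± 0.23). Gibberellin genes had 4 of 10 higher and 3 lower, with GASA6 at 2.41 ± 0.09. The circadian clock list had 2 of 12 higher and 5 lower, floral transition and flower 1 of 5 each way, root markers 1 of 7 each way, and flavonoid and anthocyanin 1 of 2 lower (CHI -1.03 ± 0.24). For BR inactivation, BR signalling, gibberellin, cell cycle, clock, floral, root and flavonoid lists the camera test was not passed (adjusted p of 0.069 or more). BR inactivation and BR signalling had positive medians (log2 0.31 and 0.08), means of 0.04 and -0.24 and a camera direction towards lower expression. The clock, floral and root lists had negative medians and means and a camera direction towards higher expression. Adjusted over the list alone, BR signalling had 8 higher, growth bHLH factors 7 higher and root markers 0 lower, and the counts of the other lists did not change.

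Of 18378 genes tested in 7-day cpd, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment placed 5098 higher and 5426 lower with BL, and 508 and 881 of them by at least 2-fold. With the larger spread of the 24-day libraries assumed for the same counts, an alternative chosen after the data were seen, 2321 genes were higher and 2623 lower.

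**Figure D3:**
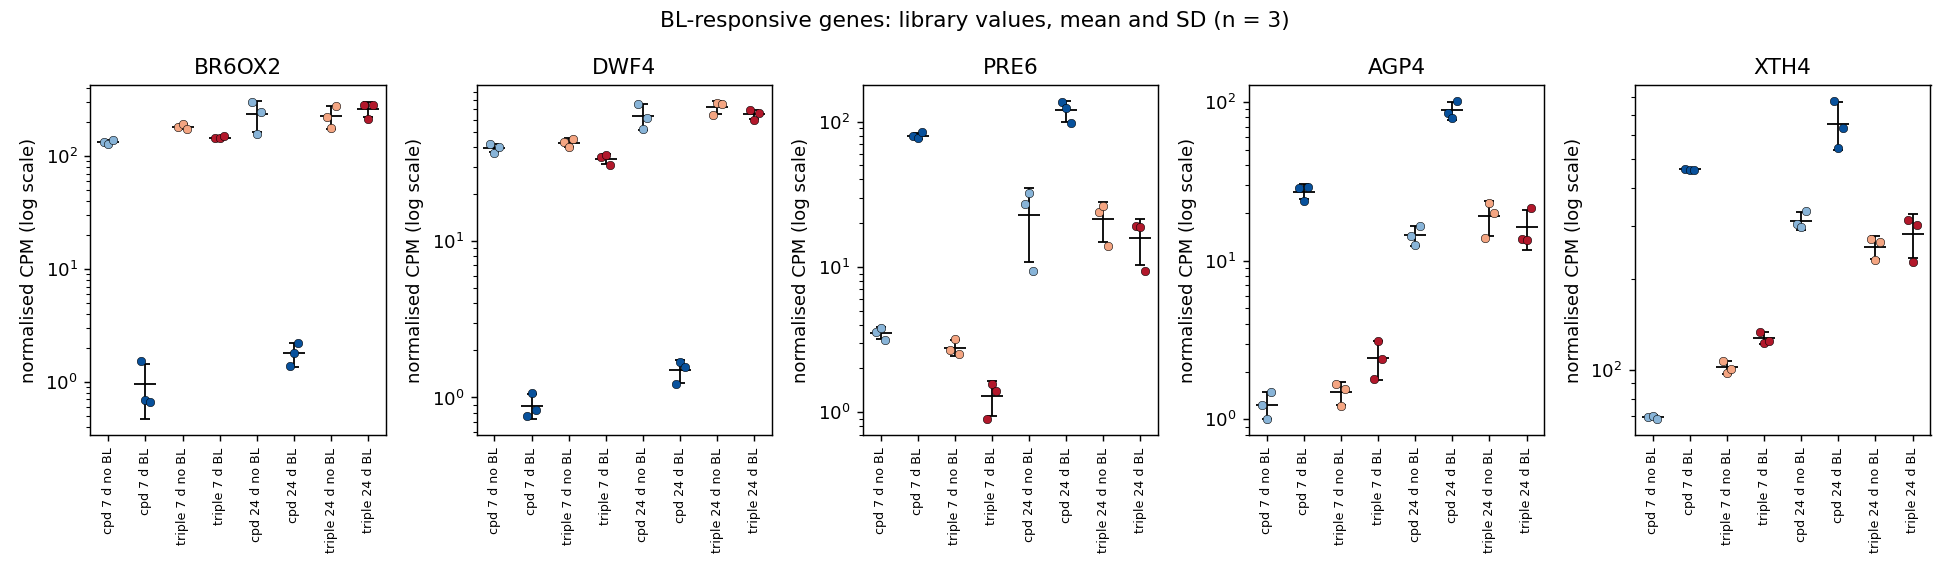
Normalised CPM (log scale) of BR6OX2, DWF4, PRE6, AGP4 and XTH4 in the 8 groups, with points for libraries, horizontal ticks for means and bars for SD (n = 3). With BL, BR6OX2 lies at 0.958 CPM in 7-day cpd and 1.8 CPM in 24-day cpd, and at 147 and 262 CPM in the triple mutant.

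In 24-day cpd, BL again lowered BR biosynthesis genes and raised SAUR genes. BR6OX2 went from 237 ± 73 to 1.8 ± 0.43 CPM (SD, n = 3; log2 -7.04 ± 0.32, SE) and DWF4 fell 41.9-fold. The ethylene biosynthesis gene ACS11 went from 20.4 ± 4.5 to 0.104 ± 0.0062 CPM, MYB55 fell 87.9-fold to 0.162 ± 0.2 CPM, and BEH2 and ROT3 fell 12.3-fold and 12.2-fold. With BL, ACS11 and MYB55 lay at or under the floor of 0.146 to 0.174 CPM of a 24-day library, so the sizes of their falls are uncertain. The largest rises under the naming rule, which asks for a mean of at least 5 CPM, were SAUR9 6.62-fold, SBP3, a selenium-binding protein gene, 6.48-fold, AGP4 6.12-fold, XTH8 5.35-fold, the tubulin gene TUB1 5.32-fold and PRE6 5.22-fold. PRE6 had the largest adjusted p of the 12, 0.00355.

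By list, 6 of 7 BR biosynthesis genes fell (7 adjusted over the list alone) and 16 of 16 SAUR genes rose (also 16 adjusted over the list alone, and 14 of 15 with the reference loci of SAUR21 and SAUR68). SAUR16 rose 6.45-fold and SAUR10 rose 23.7-fold. Expansins and xyloglucan enzymes had 9 of 17 higher and 2 lower (10 and 2 adjusted over the list alone), with EXPA11 at log2 1.57 ± 0.17 and XTH24 at -0.97 ± 0.12. BR signalling had 1 of 19 higher and 5 lower (3 and 5 adjusted over the list alone), led by BEH2 and BRI1 (-1.26 ± 0.10), with a median of log2 0.08, a mean of -0.34 and a camera call towards lower expression. Camera gave an adjusted p of at most 0.0024 for these 4 lists and of at most 0.039 with an estimated correlation. Senescence genes fell in 4 of 8 cases (6 lower and 1 higher adjusted over the list alone), led by the chlorophyll breakdown gene PAO (-0.51 ± 0.07), with a camera adjusted p of 0.0013 and an adjusted p = 0.058 with an estimated correlation. With the replicate number as a block, the lists of growth bHLH factors (3 of 8 higher, 1 lower), cellulose synthases (3 of 8 higher), ABA response and metabolism (1 of 17 lower, ABI5 at -1.40 ± 0.16) and cell cycle (1 of 13 higher) also passed camera, with adjusted p-values of 0.018, 0.033, 0.022 and 0.032 in place of 0.24, 0.075, 0.08 and 0.075. Member counts of these 4 lists are from the fit without the block. There camera gave adjusted p = 0.73, 0.17, 0.68 and 0.35 with an estimated correlation, and the blocked test was not run with one. Adjusted over the list alone, these 4 lists had 4 higher and 1 lower, 5 higher and 1 lower, 1 lower, and 4 higher and 1 lower. Photosynthesis had 1 of 21 higher, jasmonate and defence had 0 of 14 and 0 of 12 past edgeR's test, and adjusted over the list alone these counts were the same.

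Of 19731 genes tested in 24-day cpd, edgeR placed 895 higher and 1023 lower, and 183 and 235 by at least 2-fold. With the replicate block the counts were 1476 and 1574. They fell to 452 and 621 without replicate 1 of untreated cpd, 419 and 616 without its replicate 2, 407 and 510 without replicate 1 of BL-treated cpd and 556 and 642 without its replicate 2, and were 449 and 617 with replicate 3 left out of every group, an alternative chosen after the data were seen.

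The BL responses of cpd at the 2 ages overlapped. Among 18134 genes tested at both ages, 729 were higher at both (241 expected from independent lists, Fisher's exact test, two-sided, p = 1.2e-278) and 850 were lower at both (294 expected, p = 1.07e-315), while 35 were called in opposite directions. The 2 comparisons share no library. Log2 fold changes correlated across genes with r = 0.70 and rho = 0.56. Genes are not independent replicates, so neither these values nor the Fisher p-values measure a spread between plants. The expected counts also take no account of expression level. The fall of BR6OX2 and DWF4 differed between ages by log2 0.06 ± 0.46 and 0.07 ± 0.28 (SE), neither past the test (adjusted p = 0.966 and 0.921). The fall of ROT3 was smaller at 24 days by log2 1.72 ± 0.30, and in the BR biosynthesis list 2 of 6 effects were higher at 24 days (3 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.12 with an estimated correlation). The rises of PRE6, XTH8 and AGP4 were smaller at 24 days by log2 -2.13 ± 0.49, -1.78 ± 0.28 and -1.84 ± 0.36 (largest adjusted p = 0.00791). These are differences in fold, and untreated levels differed too. PRE6 had 3.151 to 3.814 CPM in untreated 7-day cpd and 9.343 to 32.13 CPM at 24 days. With BL it had 76.87 to 84.33 and 98.23 to 136.7 CPM. CPM was normalised within each age, so levels compare only roughly between ages. The BL effects on JAZ1 and MYB51, which fell at 7 days, differed between ages by 1.37 ± 0.24 and 1.03 ± 0.10. In the photosynthesis list 10 of 21 genes had a lower BL effect at 24 days (17 adjusted over the list alone; camera adjusted p = 2.2e-10, and adjusted p = 0.12 with an estimated correlation). With the replicate block, BR inactivation (0 of 6, 1 higher adjusted over the list alone) and expansins and xyloglucan enzymes (2 of 17 higher and 3 lower, 3 and 3 adjusted over the list alone) passed camera with adjusted p-values of 0.049 and 0.025 in place of 0.15 and 0.072. Member counts of both lists are from the fit without the block, where camera gave adjusted p = 0.21 and 0.17 with an estimated correlation. The age interaction was fitted with 1 spread for both ages, a coefficient of variation of 10.9%, against 15% at 24 days and 2.01% at 7 days. Its SEs and p-values can thus be too small for the 24-day part. The same fit placed 1985 genes higher and 2133 lower for BL in 24-day cpd, against 895 and 1023 in the fit of the 24-day libraries. In all, 1099 of 19935 genes had a higher and 830 a lower BL effect at 24 days than at 7 days, and 1670 and 1276 with the replicate block. The count of lower effects was 464 without replicate 2 of BL-treated 24-day cpd and 544 without replicate 1 or 2 of untreated 24-day cpd. It was 521 and 540 without replicate 2 and 3 of untreated 7-day cpd, and 528, 548 and 540 without replicate 1, 2 and 3 of BL-treated 7-day cpd.

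In the 7-day triple mutant, many transcripts differed between BL-treated and untreated seedlings by small amounts. BR6OX2, DWF4, ROT3 and CPD fell by 0.32 ± 0.04, 0.34 ± 0.06, 0.43 ± 0.07 and 0.17 ± 0.03 (SE) on the log2 scale. Under the naming rule, with its mean of at least 5 CPM, the largest rises were in UGT73C1, a glycosyltransferase gene (log2 1.73 ± 0.17, from 2.74 ± 0.78 to 9.02 ± 0.31 CPM, SD, n = 3), APR2 of sulfate assimilation (1.11 ± 0.06), the glutathione transferase gene GSTU24 (1.09 ± 0.08), UGT75B1 (1.07 ± 0.08) and the superoxide dismutase gene FSD1 (1.06 ± 0.10). The defence gene PR1, below that level, rose by log2 1.47 ± 0.28. UGT76E2 fell by 1.25 ± 0.10, EXO70H2 fell by 0.97 ± 0.06 and the defence kinase gene FRK1 fell by 0.90 ± 0.06. PRE6 fell from 2.78 ± 0.35 to 1.29 ± 0.35 CPM.

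By list, 18 of 21 photosynthesis genes rose (median log2 0.26; LHCB3 0.54 ± 0.03, LHCB1.1 0.47 ± 0.03). Jasmonate genes fell in 10 of 14 cases (AOS -0.49 ± 0.03, JAZ1 -0.40 ± 0.03), glucosinolate biosynthesis genes in 8 of 14 (CYP83B1 -0.51 ± 0.03) and BR biosynthesis genes in 5 of 6 (median -0.33). Expansins and xyloglucan enzymes had 7 of 14 higher and 2 lower (XTH9 0.41 ± 0.04, EXPA10 -0.75 ± 0.07). Camera gave an adjusted p of at most 0.003 for these 5 lists and of at most 0.029 with an estimated correlation. Growth bHLH factors fell in 6 of 8 cases (camera adjusted p = 0.0082, and adjusted p = 0.2 with an estimated correlation), and circadian clock genes rose in 5 of 12 and fell in 1 (camera adjusted p = 0.011, and adjusted p = 0.055 with an estimated correlation). Of 16 SAUR genes 0 passed edgeR's test (median log2 -0.06, mean 0.11, camera direction lower, adjusted p = 0.84), where 6035 of all genes had an unadjusted p under 0.05. Adjusted over the list alone, photosynthesis had 19 higher, expansins and xyloglucan enzymes 8 higher and clock genes 7 higher, and the other counts named here did not change.

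Of 18378 genes, edgeR placed 2098 higher and 2018 lower with BL in the 7-day triple mutant, 50 and 58 of them by at least 2-fold, with a median absolute log2 change of 0.27 among those called. DESeq2 placed 1179 higher and 1340 lower, a fit of all 24 libraries 188 and 202, and with the 24-day spread assumed, chosen after the data were seen, 41 were higher and 46 lower and 53 of the 63 named genes no longer passed.

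In the 24-day triple mutant, no transcript passed the test for a BL effect. BR6OX2 had 227 ± 53 CPM without and 262 ± 40 CPM with BL (SD, n = 3), DWF4 had 72.1 ± 7 and 64.7 ± 4.6 CPM, CPD had 380 ± 44 and 381 ± 29 CPM, and PRE6 had 21.3 ± 6.5 and 15.8 ± 5.5 CPM. Of 19731 genes, 0 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 773 had an unadjusted p under 0.05, and DESeq2 also placed 0 past the threshold. Adjusted over the list alone, 1 gibberellin gene was lower and the other 20 lists had 0 members past the test. The jasmonate list had a median of log2 -0.52 and passed camera (adjusted p = 0.00024, and adjusted p = 0.68 with an estimated correlation), and BR inactivation, cellulose synthases and ABA response and metabolism each had an adjusted p of 0.048 (0.29, 0.29 and 0.68 as adjusted p with an estimated correlation). Without replicate 2 of the untreated triple mutant, left out after the data were seen, none of these 4 lists passed (adjusted p = 0.85, 0.23, 0.17 and 0.85).

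The difference in BL response between genotypes was tested as an interaction. At 7 days the BL effect on BR6OX2 was higher in the triple mutant than in cpd by log2 6.78 ± 0.12 (SE), that on DWF4 by 5.12 ± 0.17 and that on CPD by 2.54 ± 0.07, while the effects on PRE6, AGP4 and XTH4 were lower by -5.61 ± 0.29, -3.72 ± 0.36 and -2.41 ± 0.05. At 24 days the same genes differed by 7.25 ± 0.39, 5.23 ± 0.22, 2.35 ± 0.16, -2.82 ± 0.57, -2.84 ± 0.30 and -0.93 ± 0.20 (largest adjusted p = 0.0357). For LHCB3 and CYP83B1 the 7-day effects in the 2 genotypes differed by 0.07 ± 0.04 and 0.06 ± 0.04, not past the test (adjusted p = 0.232 and 0.222). In their lists other members differed at 7 days: photosynthesis had 3 of 21 effects higher and 13 lower in the triple mutant (also adjusted over the list alone; camera adjusted p = 0.0031, and adjusted p = 0.21 with an estimated correlation), and glucosinolate biosynthesis had 5 of 14 higher (also adjusted over the list alone; camera adjusted p = 0.16). Jasmonate had 7 of 14 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.072 with an estimated correlation). By list, 5 of 6 BR biosynthesis genes had a higher effect in the triple mutant at 7 days and 5 of 7 at 24 days (5 and 6 adjusted over the list alone). SAUR genes had a lower effect in 12 of 16 cases at 7 days (12 adjusted over the list alone; camera adjusted p = 0.0017, and adjusted p = 0.069 with an estimated correlation) and in 7 of 16 at 24 days (16 adjusted over the list alone; 2e-22, and adjusted p = 0.044 with an estimated correlation). Senescence genes had a higher effect in 7 of 8 cases at 7 days (7 adjusted over the list alone; camera adjusted p = 3.6e-05, and adjusted p = 0.026 with an estimated correlation) and in 2 of 8 at 24 days (5 higher and 1 lower adjusted over the list alone; 0.0024, and adjusted p = 0.056 with an estimated correlation). With the replicate block at 24 days, growth bHLH factors (1 of 8 higher and 2 lower, 1 and 4 adjusted over the list alone) and jasmonate (0 of 14, also 0 adjusted over the list alone) passed camera with adjusted p-values of 0.0071 and 0.044 in place of 0.19 and 0.084. Member counts of both lists are from the fit without the block, where camera gave adjusted p = 0.7 and 0.92 with an estimated correlation. Over all genes, 4097 effects were higher and 3439 lower in the triple mutant at 7 days, and 1111 and 806 with the 24-day spread assumed. At 24 days 314 were higher and 229 lower, 657 and 548 with the replicate block, and 580 and 495 with DESeq2. The 24-day counts fell to 146 and 109 with replicate 3 left out of every group, chosen after the data were seen. They fell to 200 and 140 without replicate 1 of untreated cpd, 193 and 145 without replicate 1 of the untreated triple mutant and 199 and 127 without replicate 1 of BL-treated cpd, and the count of lower effects fell to 135 without replicate 2 of untreated cpd and 143 without replicate 3 of the BL-treated triple mutant.

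**Figure D4:**
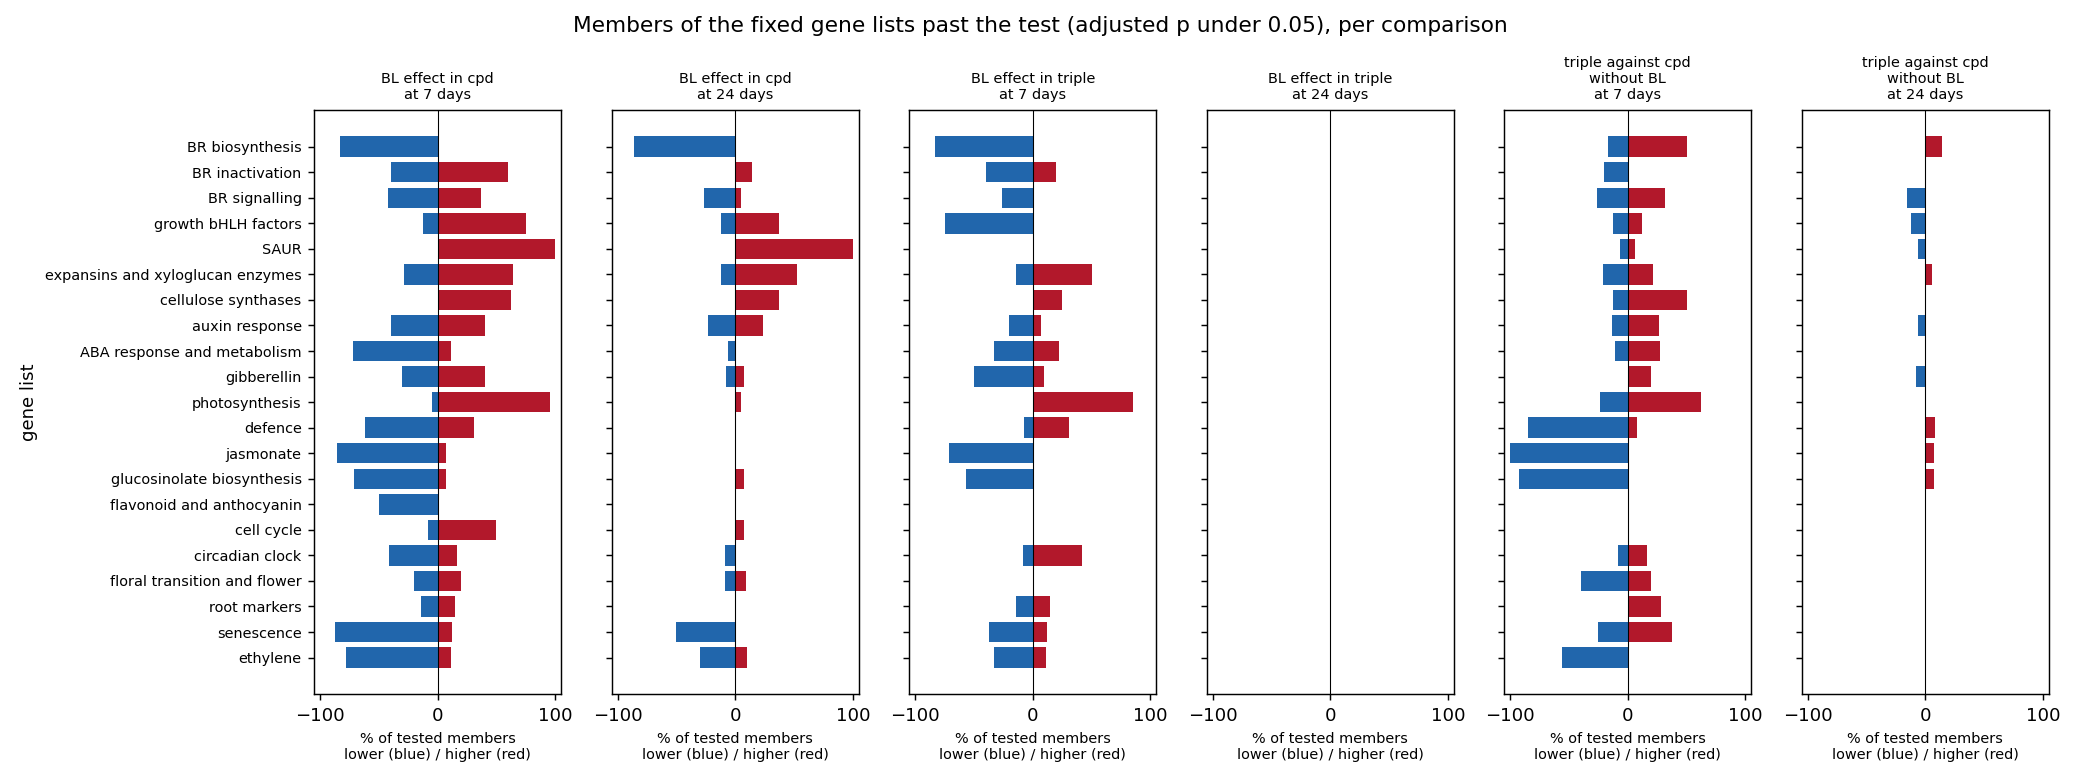
Share of the tested members of each of the 21 fixed lists that were higher (red, to the right) or lower (blue, to the left) past edgeR's test, in percent, for the 6 comparisons. All 16 SAUR genes were higher with BL in cpd at both ages, 14 of 14 jasmonate genes were lower in the 7-day triple mutant than in cpd, and 0 members passed for BL in the 24-day triple mutant.

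Without BL, the 7-day triple mutant differed from cpd in defence, jasmonate and glucosinolate genes besides the mutated genes. The 24 libraries hold no wild type. Rises and falls between genotypes, at either age, are thus only relative to cpd, and which mutant departs from wild type cannot be told. FRK1 fell from 158 ± 6.7 CPM in cpd to 56.8 ± 1.6 CPM in the triple mutant (SD, n = 3; log2 -1.48 ± 0.04, SE), and the salicylate biosynthesis genes ICS1 and PBS3 fell by 1.31 ± 0.10 and 2.14 ± 0.10. MAF5, a relative of the flowering repressor FLC, went from 16.7 ± 0.72 to 1.33 ± 0.38 CPM, and AIG1 fell 3.79-fold. HEI10, the glycine-rich protein gene GRP9, FSD1, MLP328 and the cold-regulated gene COR15B were 4.46-fold, 3.66-fold, 2.80-fold, 2.56-fold and 2.47-fold higher. Defence genes fell in 11 of 13 cases and rose in 1, jasmonate genes fell in 14 of 14 (median log2 -0.28; JAZ8 -1.05 ± 0.08), glucosinolate biosynthesis genes in 13 of 14 (median -0.70; 14 adjusted over the list alone) and ethylene genes in 5 of 9 (ACS8 -0.87 ± 0.04). ABA response and metabolism had 5 of 18 higher and 2 lower (6 and 2 adjusted over the list alone), led by the cold- and ABA-responsive genes COR15A (1.28 ± 0.04) and COR47 (0.46 ± 0.02). Camera gave an adjusted p of at most 0.00015 for these 5 lists and of at most 0.024 with an estimated correlation, and adjusted over the list alone the counts of defence, jasmonate and ethylene did not change. BR biosynthesis had 3 of 6 higher and 1 lower (also adjusted over the list alone), with CPD, the gene mutated in cpd, 6.35-fold and BR6OX2 1.37-fold higher. Of 18378 genes, edgeR placed 2377 higher and 2755 lower in the triple mutant, 88 and 194 by at least 2-fold. A fit of all 24 libraries gave 358 and 673, DESeq2 placed 1528 higher, and with the 24-day spread assumed 100 were higher and 313 lower and 41 of the 59 named genes no longer passed.

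Without BL at 24 days, the receptor genes BRL3, BRI1 and BRL1 fell 5.60-fold, 4.15-fold and 2.32-fold in the triple mutant, and CPD was 3.37-fold higher. SAUR67, with a mean under 5 CPM, fell 3.65-fold. Under the naming rule the largest rises were RAS1 (5.81-fold), PP2-B13 (4.49-fold), the mitochondrial carrier gene DIC2 (4.14-fold), PP2-B14 (log2 2.04 ± 0.28, SE), the transcription factor gene ERF11 (1.97 ± 0.39) and the nudix hydrolase gene NUDT21 (42.4 ± 4.7 CPM in cpd, 164 ± 30 CPM in the triple mutant, SD, n = 3). In the defence list 1 of 12 rose, WRKY33 (0.94 ± 0.18), and 2 rose adjusted over the list alone (camera adjusted p = 0.61). In the jasmonate list 1 of 14 genes rose, JAZ1 (1.28 ± 0.24), and 10 rose adjusted over the list alone, with a median of log2 1.12. Replicate 2 of the untreated triple mutant had the highest jasmonate median of the 12 libraries, 1.27 log2 units above their mean, and the list median was 0.60 without it. Camera gave the jasmonate list an adjusted p of 6e-09 and an adjusted p = 0.4 with an estimated correlation. Glucosinolate biosynthesis had 1 of 14 higher (1 adjusted over the list alone; MYB51 0.69 ± 0.10; camera adjusted p = 0.00011, and adjusted p = 0.4 with an estimated correlation). BR signalling had 3 of 19 lower, the mutated receptor genes themselves (4 adjusted over the list alone), and a median of log2 -0.04. Camera placed it lower (adjusted p = 3.5e-05, and adjusted p = 0.023 with an estimated correlation). In the BR biosynthesis list 1 of 7 genes rose (2 adjusted over the list alone), CPD, the gene mutated in cpd. The list had a median of log2 0.19 and a mean of 0.39, so its rise rests in part on the choice of mutant. BR biosynthesis (higher), SAUR, growth bHLH factors and photosynthesis (lower) had camera adjusted p-values of 2.5e-05, 7.1e-05, 0.011 and 0.0058. With an estimated correlation these were 0.052, 0.4, 0.4 and 0.51. Root markers had 0 of 12 past edgeR's test (0 adjusted over the list alone) and a median of log2 0.38, with a camera adjusted p of 0.19, and 0.032 without that library. With an estimated correlation and all libraries the root markers had an adjusted p = 0.69. Of 19731 genes, edgeR placed 156 higher and 50 lower and DESeq2 760 and 301, and the replicate block gave 992 and 430. Each library left out moved the total of 206, to 15, 47 and 416 without replicate 1, 2 and 3 of untreated cpd and to 40, 53 and 1123 without replicate 1, 2 and 3 of the untreated triple mutant. A fit of these 6 libraries alone gave 12 and 2, with 16 of the 20 named genes no longer past the test, a fit of all 24 libraries 1485 and 1331, and replicate 3 left out of every group, chosen after the data were seen, 763 and 266.

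**Figure D5:**
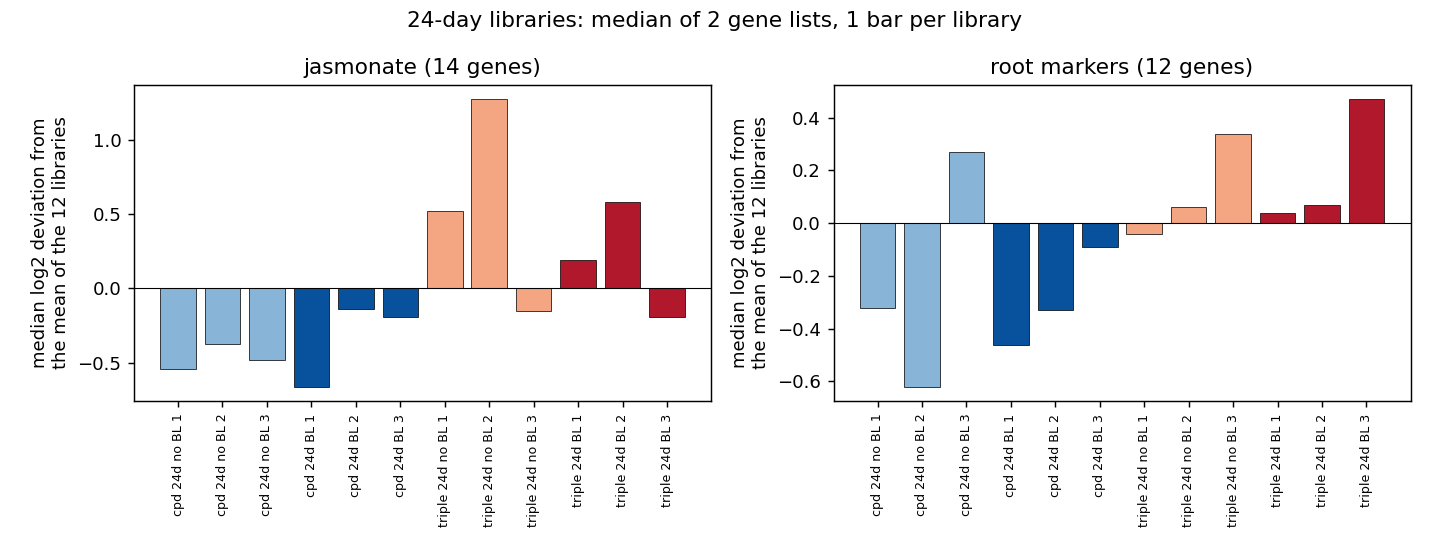
Median log2 deviation of the jasmonate list (14 genes) and the root marker list (12 genes) from the mean of the 12 libraries of 24-day seedlings, with a bar per library coloured by group. The jasmonate median is highest in replicate 2 of the untreated triple mutant (1.27), and the root marker median is highest in replicate 3 within each group.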

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

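Tests of replicate spread, of a smaller copy of the response of cpd, of root tissue, of library depth and of the jasmonate list were chosen after the results were seen, whereas those of GC content and length, of time of day and of other splits of the libraries were written beforehand.

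The BL effect differed between genotypes at 7 days, tested as an interaction, for 4097 genes with a higher and 3439 with a lower effect in the triple mutant and for 124 of the named genes. Of 33 regroupings of the BL labels within genotypes only the real 1 gave as many genes (7536). The 27 that broke the real BL split in both genotypes gave 0 at most. Those that kept the split of cpd and broke that of the triple mutant gave 6745, 6835 and 6883 genes. Regrouping removes the BL effect itself, and most calls stayed where cpd kept its own effect. This share therefore cannot decide whether the difference between genotypes is chance. At 24 days 314 effects were higher and 229 lower, with 39 named genes. There 4 of 33 regroupings gave as many (543 genes, highest other 670). The 3 others kept the BL split of cpd intact and so still held its BL effect, and the 22 that broke both splits gave at most 26 genes. The 24-day share therefore cannot decide about chance either. Of the 8 others that part all 6 pairs of replicate numbers, as the real labels do, 1 gave as many (596 genes). In the fit with 1 spread for both ages, the BL effect in cpd differed between ages for 57 named genes. Over all genes it was higher at 24 days for 1099 and lower for 830. For ages 3 of 33 regroupings gave as many (1929 genes, highest other 3705). Both others kept the 7-day split intact and so still held the 7-day BL effect, and the 27 that broke both splits gave 0 genes. This share therefore cannot decide whether the difference between ages is chance.

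For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real split gave 10524 genes for BL in 7-day cpd, 1918 in 24-day cpd, 4116 in the 7-day triple mutant, 5132 for genotype at 7 days and 206 for genotype at 24 days, each in 1 of 10 splits with 0 as the highest other. For BL in the 24-day triple mutant all 10 of 10 splits gave 0 genes in edgeR's test (773 at an unadjusted p under 0.05, 0 with DESeq2). Where replicate numbers pair the libraries, at 24 days, 3 other splits part as many pairs as the real one, and each gave 0 genes.

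The 7-day triple mutant, whose BR receptor genes are mutated per its label, had 4116 genes called for BL. Bias from GC content and gene length as the whole cause is argued against, since the correction moved log2 fold changes by a median of 0.00849, against a median size of 0.27 among the calls, and 96.5% of the calls were kept in the same direction. Replicates that vary little more than counting noise may let very small differences between seedlings pass the test, which stays open: 87 genes passed with the 24-day spread assumed (2.11%), but effects of this size would mostly be lost at that spread whether real or not. A smaller copy of the response of cpd is another candidate explanation. Of 1579 genes called the same way in cpd at both ages, 550 were called in the triple mutant, and 74.9% of these went as in cpd. The interval was 71.1% to 78.5% (exact Clopper-Pearson, over genes, which are not independent), and the slope over the 1579 was 0.05. Whether such a copy would come through remaining receptor function was not tested. Other genes went against cpd, such as PRE6 (log2 -1.09 against 4.51), and effects over all genes correlated with r = 0.19. Of 16 SAUR genes 0 passed in the triple mutant, where 16 rose in cpd. Growth bHLH factors fell in 6 of 8 cases, where 6 of 8 rose in cpd, while BR biosynthesis genes fell in 5 of 6 cases in both genotypes. The explanations named here cannot be told apart, since nothing says whether the replicates were grown separately, and others were not tested.

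Replicate 3 had the highest second principal component within each 24-day group, while in both triple mutant groups replicates 1 and 3 were the closest pair by counts (15.8 without and 14.4 with BL, chi-square per degree of freedom) and replicate 2 lay farther from both. Another time of day at harvest is argued against, since the clock index of replicate 3 lay over 0.5 from the others in 1 of 4 groups. Lower library depth is argued against, since replicate 3 had the lowest total in 2 of 4 groups. A larger share of root tissue may contribute, since root markers had their highest median in replicate 3 in 4 of 4 groups. The labels name no batch, and no explanation beyond those named here was tested.

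The jasmonate list had a median of log2 1.12 in the untreated triple mutant against cpd at 24 days, with 1 of 14 members past the test, a camera adjusted p of 6e-09 and an adjusted p = 0.4 with an estimated correlation. Replicate 2 of the untreated triple mutant may carry part of this median, since the median was 0.60 without it. A genotype difference that does not depend on BL is another candidate explanation, since the median between the BL-treated groups was 0.62. That value is not independent of the first explanation, since replicate numbers pair the 24-day libraries (r = 0.421 between replicate 2 of the untreated and the BL-treated triple mutant), and with the replicate block the median was 1.03. How much each adds stays open with 3 libraries per group.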

How the results depend on the processing

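The 24-day spread, the omission of replicate 3 and list tests with the replicate block or without 1 library were chosen after the data were seen, and the other alternatives were planned. Over 262 named gene comparisons and 3405 alternative values, 3071 stayed on the same side of the threshold and 334 were no longer past it. Where the main result was past it, 0 reversed direction. For the other comparisons direction was not checked. Losses gathered in the 7-day triple mutant with BL (53 of 63 named genes with the 24-day spread, 36 with all 24 libraries in one fit), genotype at 7 days (41 of 59 and 31) and genotype at 24 days (16 of 20 with only the groups compared). With each library left out in turn, 55 values of the 20 named genes for genotype at 24 days and 38 values of the 47 for BL in 24-day cpd were no longer past it. RLE size factors and no filter moved no count of calls by over 1.5 times. For the counts that moved, given as higher and lower, the cause was not tested unless named. The 24-day spread raises the spread by construction, and it came with a likelihood ratio test in place of the quasi-likelihood test. With it the counts were 2321 and 2623 for BL in 7-day cpd, 41 and 46 in the 7-day triple mutant, 100 and 313 for genotype at 7 days and 1111 and 806 for the 7-day interaction. With all 24 libraries in one fit, which shares 1 spread between ages, they were 1985 and 2133 for BL in 24-day cpd, 188 and 202 in the 7-day triple mutant, and 358 and 673 at 7 days and 1485 and 1331 at 24 days for genotype. DESeq2 gave 1179 and 1340 for BL in the 7-day triple mutant, 1528 higher for genotype at 7 days, 760 and 301 at 24 days, and 580 and 495 for the 24-day interaction. The replicate block gave 1476 and 1574 for BL in 24-day cpd, 992 and 430 for genotype at 24 days, 657 and 548 for the 24-day interaction and 1670 and 1276 for the age interaction, and it moved no other count by over 1.5 times. At 7 days 0 of 12 libraries correlated best with their own number in every group, and 7 of 12 at 24 days. Only the groups compared gave 12 and 2 for genotype at 24 days. With replicate 3 left out of every 24-day group, the counts were 449 and 617 for BL in cpd, 763 and 266 for genotype and 146 and 109 for the interaction. With each library left out in turn, BL in 24-day cpd gave 407 to 653 and 510 to 975, genotype at 24 days 10 to 837 and 5 to 286, the 24-day interaction 193 to 390 and 127 to 315, and the age interaction 737 to 1335 and 464 to 1098. The counts for BL in the 24-day triple mutant were 0 under each alternative run (773 genes at an unadjusted p under 0.05 in edgeR). At a threshold of 0.01, 681 genes were called the same way in cpd at both ages. Of 74 list tests past the threshold 37 remained past it with an estimated correlation. The replicate block brought 9 more list tests past it and took 0 away, among them expansins and xyloglucan enzymes for genotype at 7 days (adjusted p = 0.043 in place of 0.051), where the numbers did not pair. ABI4 had 0 counts in all 24 libraries, and whether depth or the way its locus was counted lies behind this was not tested.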

Other observations

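Some genes that rose with BL in the 7-day triple mutant fell with BL in 7-day cpd. UGT73C1 fell by 2.22 ± 0.26 (SE) on the log2 scale in cpd, APR2 fell by 0.91 ± 0.07, GSTU24 fell by 1.47 ± 0.12, UGT75B1 fell by 1.19 ± 0.10 and UGT73C5, which inactivates BRs, fell by 1.1 ± 0.06. The interaction was log2 3.95 ± 0.31, 2.02 ± 0.09, 2.57 ± 0.15, 2.26 ± 0.13 and 1.80 ± 0.08. Each gene was named by the fixed rule, and setting them side by side was chosen after their values were seen.

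MAF5 had 16.7 ± 0.72 CPM in untreated 7-day cpd and 1.33 ± 0.38 CPM in the untreated triple mutant (SD, n = 3), and 0.478 ± 0.16 and 0.599 ± 0.097 CPM at 24 days.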
